A study of Homo sapiens with 32 samples.

How the data were processed

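N6-methyladenosine (m6A) was mapped in PANC-1, an established human pancreatic ductal adenocarcinoma cell line. RNA fragments bound by an anti-m6A antibody were sequenced beside input RNA, which was not selected with the antibody. Per the labels' protocols, the RNA was total RNA, an aliquot of the fragments served as input, and sequencing was paired-end. The labels give 32 samples, of which 12 stand behind the 3 peak lists used here: control, CFL1 knockout and METTL3 knockout, each with 2 antibody samples and 2 inputs. The other 20 samples, from nuclear RNA and from cytochalasin D treatment with its untreated control, were not analysed here. Samples were grouped by their titles, because a treatment label of the control antibody samples reads as if no antibody had been used.

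Each list holds peaks called with MACS2, after alignment with STAR to hg19, per the submitters' processing notes, which also name bedtools. Versions and settings, and whether input served as the background of the calls, are not given in the sources used here. The deposited values per peak are its interval, the position of its summit, a fold enrichment, which is a ratio, and −log10 p and −log10 q. They are the authors' own values and were used here to describe, rank or filter peaks, and to count the peaks of each library above a threshold. Those counts were compared between groups at the same threshold, although −log10 q may vary with read depth, which is unknown. The columns of score and −log10 p were the 2 value columns not used.

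The names of the peaks show that each list joins the peaks of 2 libraries that were called separately. The libraries are called by the number in those names: control 1 and 2, CFL1 knockout 3 and 5, and METTL3 knockout 3 and 5. The knockout numbers are not the replicate numbers of the labels. The names of the knockout libraries also carry the letters si, while the labels call them knockouts. The labels were followed, and what the letters stand for is not given in the sources used here. Peak lists do not show whether either protein was absent, which was not checked. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the spread between them may be technical. Peak numbers within the names skip values, and 22.5% and 28.6% of the numbers up to the highest were missing in control 1 and 2. The share missing was 50.2% and 42.0% in CFL1 knockout 3 and 5, and 44.0% and 41.8% in METTL3 knockout 3 and 5. The criterion for this removal is not given in the sources used here.

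The overlap shares, the odds ratio, the rule for named peaks and most alternatives were chosen before the data were examined. They assumed that each list pooled its replicates. Window counts were scaled to 100000 peaks per library, and a window entered if the mean of its control and knockout counts was at least 20. The comparisons between libraries, the chromosome and window counts and the tests of explanations were added after seeing the data, as were the alternatives on peaks per library, on peaks found in both libraries and on chromosomes 1 to 22. The bounds of the copy tests were set after the lists had been examined but before copies were counted. In each list, lines with the same interval were collapsed to the line with the highest −log10 q. A peak was shared if it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1), otherwise it was called lost from, or absent from, the other list. Shares have exact 95% binomial intervals, which cover counting error only, since neighbouring peaks are not independent. A site called in both libraries with different ends was counted as separate peaks, and such peaks are not independent either. Loss in both knockouts was measured as a Mantel-Haenszel odds ratio in 20 equal-size bins of control −log10 q. It was set beside 100 simulated pairs of unchanged groups, in which a control peak was found with the rate at which the other control library found peaks of its bin. This fixes the simulated odds ratio within bins at 1, so only the simulated value without bins is given. A difference between libraries was tested by exact permutation of the libraries, which treats them as exchangeable although libraries of a group resembled each other. With 2 against 2 libraries there are 3 splits and the smallest two-sided p is 0.333, and with 2 against 4 there are 15 splits and the smallest p is 0.0667, so no test could pass a threshold of 5%. Values per group are means with SD over 2 libraries. Read depth is unknown from the peak lists.

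Named peaks are, for each knockout, the 10 control peaks lost with the highest −log10 q, the 6 knockout peaks absent from control with the highest −log10 q, and the 6 control peaks kept with the highest −log10 q. They lie on chromosomes 1 to 22 and X, and a peak overlapping one already named was passed over. Values of a named peak are those of the library where it was strongest. For every lost or kept peak named, that was control 2. Positions are 1-based on hg19. An hg19 annotation or genome was not used here, so gene names, transcript regions, gene lists and the DRACH sequence motif were not computed.

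The overlap and odds ratio code was tested on simulated data made from the 156900 control intervals. It recovered a loss of 36.1% exactly, all 20000 simulated new peaks, an odds ratio of 0.989 where losses were independent, and 4.94 where an odds ratio of 5 had been set. Alternatives were a stricter overlap, the summit as position, thresholds on −log10 q and fold, merging of peaks within 100 bp, other strength bins and each library left out. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots used matplotlib 3.10.9.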

Results

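Peaks of m6A were compared between control PANC-1 cells and cells labelled as knockouts of CFL1 (cofilin 1, an actin filament-severing protein) or of METTL3 (the catalytic subunit of the m6A methyltransferase complex). The title of the series names CFL1-dependent m6A on RNA of super enhancers. The lists show which peaks were called in control and in each knockout. RNA levels in the input were not examined here, so a lost or gained peak is not by itself a change in methylation. The control list held 156900 peaks with distinct intervals, covering 47.8 Mb. The CFL1 knockout list held 138900 covering 45.8 Mb, and the METTL3 knockout list 128603 covering 42.3 Mb. A site called in both libraries of a list with different ends counts as separate peaks here and in the shares per list below. Joined where they overlapped, the peaks formed 99343, 92826 and 82279 regions, in the same order. The median peak width was 336, 335 and 352 bp in that order.

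Fewer peaks were listed for the knockouts than for control, and the order of the means turned among peaks of higher −log10 q. Control libraries held 78535 ± 1318 peaks (SD, n = 2), CFL1 knockout libraries 69512 ± 4549 and METTL3 knockout libraries 64406 ± 773. Both libraries of each knockout lay below both control libraries, and an exact permutation of 2 against 2 libraries cannot give a two-sided p under 0.333. Among peaks with a −log10 q of at least 5, control libraries held 50534 ± 436, CFL1 knockout libraries 49861 ± 3451 and METTL3 knockout libraries 45059 ± 571. At a −log10 q of at least 10 there were 32809 ± 508 in control, 35051 ± 495 in the CFL1 knockout and 33423 ± 1019 in the METTL3 knockout (SD, n = 2). There the METTL3 knockout libraries did not separate from control, as METTL3 knockout 5 held 32702 peaks against 33168 in control 2. At a −log10 q of at least 20, control libraries held 20568 ± 980 peaks, CFL1 knockout libraries 23308 ± 986 and METTL3 knockout libraries 23085 ± 764. Read depth is unknown, so these counts do not by themselves show that peaks were stronger in the knockouts. The highest number in the peak names of a library, where the numbers skip values, averaged 105754 ± 7924 in control, 130248 ± 22526 in the CFL1 knockout and 112778 ± 1661 in the METTL3 knockout. The share of numbers missing was 25.6% ± 4.33, 46.1% ± 5.82 and 42.9% ± 1.53, in the same order.

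**Figure D1:**
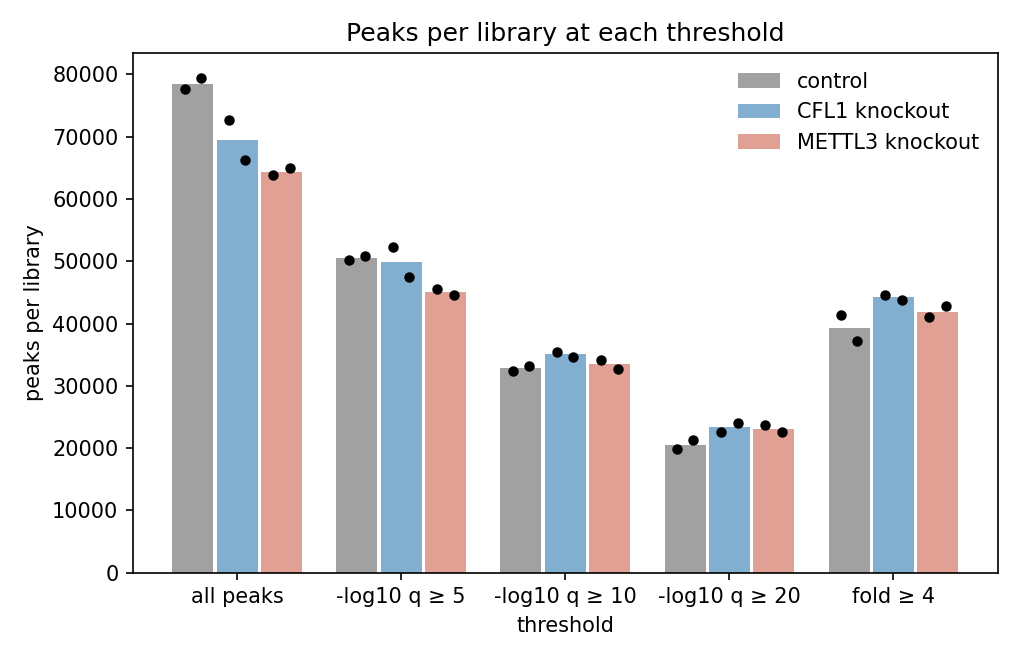
Peaks per library (y axis) at 5 thresholds (x axis). Bars are group means and points the 2 libraries of a group. At all peaks both knockouts sit below control, and at a −log10 q of at least 20 both sit above it.

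The peak positions of both knockouts stood apart from control and close to each other. The 2 control libraries shared 71.1% of their peaks (mean of both directions), against 63.4% for the 2 CFL1 knockout libraries and 69.3% for the 2 METTL3 knockout libraries. Control libraries shared a mean of 39.6% with CFL1 knockout libraries and 41.8% with METTL3 knockout libraries, while the libraries of the 2 knockouts shared a mean of 59.3% with each other. The lowest of the 4 values between the knockouts, 56.8%, lay above the highest between a knockout and control, 42.8%. Of the 15 ways to set 2 libraries against 4, control against the knockouts gave the lowest mean overlap, 40.7%, and the next lowest was 49.5% (exact permutation p = 0.0667, one-sided, the smallest possible). Most of these splits part the 2 libraries of a group, so this p-value also reflects the likeness of libraries within groups. It is no test of the groups as units. Among peaks with a −log10 q of at least 10, the control libraries shared 94.9%, the 2 knockouts 81.3%, and control shared 61.6% with the CFL1 knockout and 64.3% with the METTL3 knockout.

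**Figure D2:**
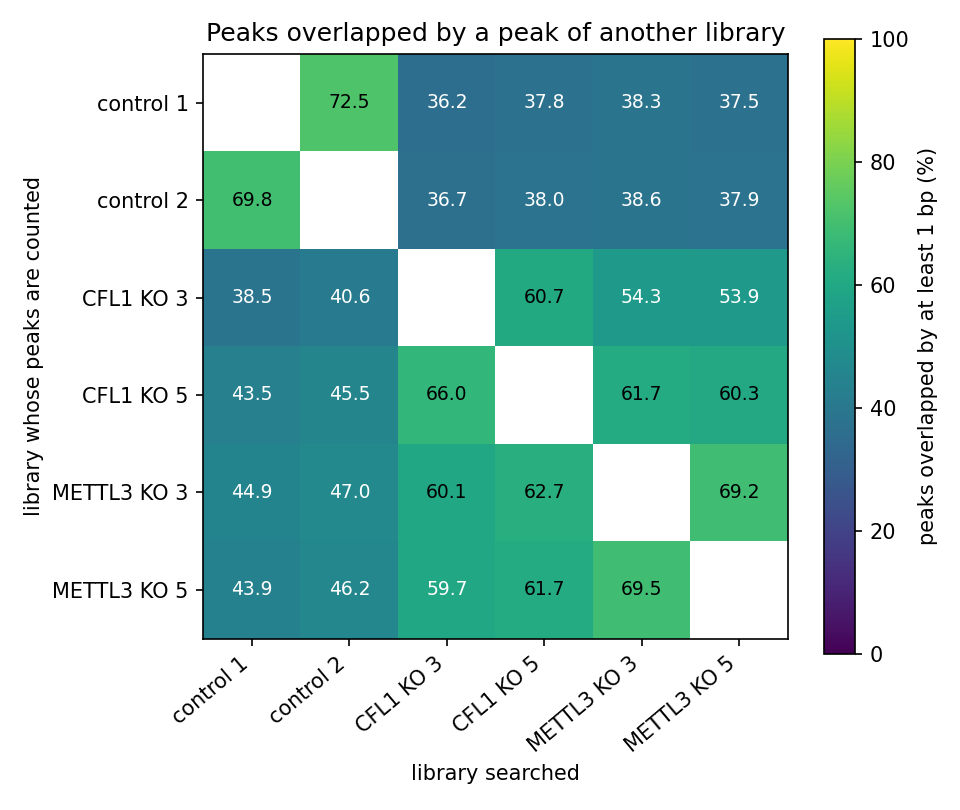
Percent of the peaks of 1 library (rows) that overlapped a peak of another library (columns) by at least 1 bp. The 2 control libraries overlap by 72.5% and 69.8%, and control peaks are found in the 4 knockout libraries at 36.2% to 38.6%.

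In the CFL1 knockout, 57.8% of control peaks had no overlapping peak (90703 of 156900, exact interval 57.6% to 58.1%). Of the CFL1 knockout peaks, 53.2% had no control peak (73882 of 138900, 52.9% to 53.5%). After merging peaks within 100 bp, which joins the calls of both libraries at a site, these shares were 62.8% and 60.4%. The strongest control peaks were nearly all kept, and the strongest lost peaks lay on chromosomes 3, 19, 18 and 6. The peak at 150262059 to 150262390 on chromosome 3 had a −log10 q of 308 and a fold of 7.06 in control 2. It was called in both control libraries and in none of the 4 knockout libraries, and the nearest CFL1 knockout peak was 22211 bp away. The peak at 40487510 to 40488340 on chromosome 19 (−log10 q 292) was also absent from all 4 knockout libraries. At 9524404 to 9524712 on chromosome 18 the control peak (−log10 q 289, fold 21.4) was absent from both CFL1 knockout libraries and present in both METTL3 knockout libraries, as was the peak at 68591459 to 68591903 on chromosome 1 (−log10 q 267). The peak at 74133729 to 74134387 on chromosome 6 (−log10 q 278, fold 14.7) was lost in both knockouts, with a CFL1 knockout peak 537 bp away.

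The other named losses in the CFL1 knockout lay at 167990979 to 167991237 on chromosome 5, 37236323 to 37236683 on chromosome 19, 125490535 to 125491137 on chromosome 11, 65441598 to 65443384 on chromosome 15 and 3805879 to 3806823 on chromosome 1, with −log10 q between 248 and 265. The peak on chromosome 15 was the widest of the 10, at 1787 bp, and had the highest fold, 24.1. All 10 were called in both control libraries, and 3 of them had a CFL1 knockout peak within 1 kb.

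The strongest CFL1 knockout peak absent from control spanned 50999406 to 51003515 on chromosome 19, with a −log10 q of 919 and a fold of 35.5. Next came 12489536 to 12490334 on chromosome 3 (−log10 q 829, fold 89.1), 92917318 to 92917951 on chromosome 5 (788, fold 18.5) and 21951331 to 21951907 on chromosome 13 (781, fold 35.3). The remaining named gains were 8054993 to 8055381 on chromosome 1 (722, fold 51.3) and 36439673 to 36440257 on chromosome 3 (644, fold 30.1). All 6 were called in all 4 knockout libraries and in neither control library, and 3 of them had a control peak within 1 kb.

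The strongest control peaks kept in the CFL1 knockout lay on chromosome 11 at 118656837 to 118657342 (−log10 q 612) and 117282721 to 117283357 (611), and on chromosome 19 at 3958476 to 3959717 (600). The others were at 66624793 to 66626556 on chromosome 11, 2435268 to 2436881 on chromosome 1 and 79218635 to 79221634 on chromosome 17. All 6 were called in all 6 libraries. Of the strongest 10% of control peaks, 95.3% had a CFL1 knockout peak, against 20.9% of the weakest 10%. At a −log10 q of at least 10 in the list counted, the share lost was 34.6% and the share of CFL1 knockout peaks absent from control 32.9%, so both depend on the threshold.

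In the METTL3 knockout, 57.7% of control peaks had no overlapping peak (90534 of 156900, exact interval 57.5% to 57.9%). Of the METTL3 knockout peaks, 49.3% had no control peak (63421 of 128603, 49.0% to 49.6%). After merging peaks within 100 bp, these shares were 62.9% and 56.1%. Of the strongest 10% of control peaks 96.6% still had a METTL3 knockout peak, against 20.5% of the weakest 10%. The 10 strongest control peaks lost included 7 that were also among the 10 named for the CFL1 knockout, on chromosomes 3, 5, 6, 11, 15 and 19. The 3 others were at 54368600 to 54368938 on chromosome 19 (−log10 q 256, fold 13.4), which both CFL1 knockout libraries kept, and at 145493529 to 145493922 on chromosome 5 (247) and 79911067 to 79911578 on chromosome 6 (235), which no knockout library held. All 10 were called in both control libraries, and 2 had a METTL3 knockout peak within 1 kb.

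The strongest METTL3 knockout peaks absent from control were at 61376386 to 61377012 on chromosome 20 (−log10 q 565, fold 18.5), 92917391 to 92917927 on chromosome 5 (556, fold 25.4) and 82973888 to 82975136 on chromosome 15 (523, fold 69.6). They were followed by 54374116 to 54374509 on chromosome 12 (504), 1700005 to 1700893 on chromosome 10 (449.9) and 24223775 to 24224548 on chromosome 22 (449). All 6 were called in all 4 knockout libraries, and 5 of them had a control peak within 1 kb. The region on chromosome 5 was also among the gains named for the CFL1 knockout. The 6 strongest control peaks kept were the same 6 as in the CFL1 knockout. At a −log10 q of at least 10 in the list counted, the share lost was 33.6% and the share of METTL3 knockout peaks absent from control 29.3%.

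**Figure D3:**
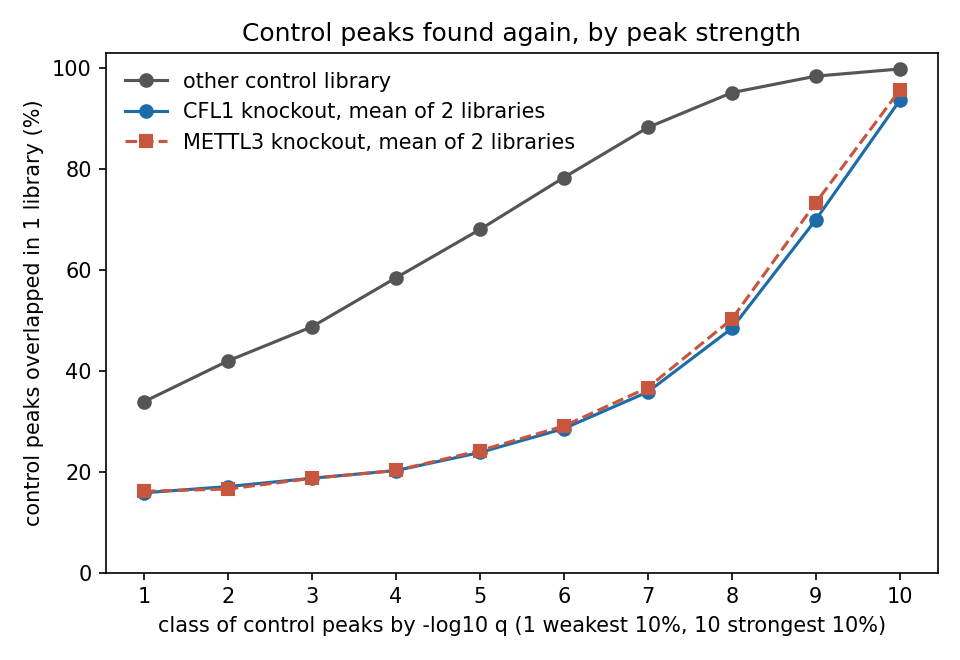
Percent of control peaks overlapped by a peak of 1 other library (y axis), in 10 equal classes of control −log10 q (x axis, 1 weakest, 10 strongest). Grey is the other control library, and blue and red are means of the 2 CFL1 and the 2 METTL3 knockout libraries. In class 8 the values are 95.1%, 48.4% and 50.2%, and in the strongest 99.8%, 93.6% and 95.6%.

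Control peaks were lost from both knockouts together far more often than from 1 alone. Of the control peaks, 52.4% (82170) were lost in both, 5.44% in the CFL1 knockout only, 5.33% in the METTL3 knockout only, and 36.9% were kept in both. Independent losses would give 52337 peaks lost in both, or 61813 within bins of control strength. The odds ratio of loss in both was 42.9 within bins and 66.6 without them, and simulated unchanged groups gave 3.51 without bins. The simulated groups lost a mean of 6594 peaks in both, so 3.51 is no benchmark for groups that differ from control. The simulation leaves out differences between peaks of like strength in how readily they are found. Both comparisons share the control libraries, and a split, which would leave 1 control library to each knockout, was not run, so part of this excess may come from them. Restricted to control peaks found in both control libraries, the odds ratio within bins was 51.7. Without that restriction but with peaks within 100 bp merged, the odds ratio within bins was 37.4. Of the peaks gained, 44.3% of the CFL1 knockout peaks absent from control overlapped a METTL3 knockout peak, and 51.8% in the opposite direction. Over all peaks the knockouts shared more, as 34.9% of the CFL1 knockout peaks had no METTL3 knockout peak and 29.6% of the METTL3 knockout peaks had no CFL1 knockout peak.

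By chromosome, the share of control peaks lost ran from 45.4% on chromosome 21 to 62.4% on chromosome 12 in the CFL1 knockout. In the METTL3 knockout it ran from 45.9% on chromosome 21 to 62.3% on chromosome 17. Chromosome 9 held 3.85% ± 0.00613 of the peaks of control libraries, 4.53% ± 0.0435 in the CFL1 knockout and 4.48% ± 0.0175 in the METTL3 knockout (SD, n = 2). Chromosome X held 2.85% ± 0.0189, 3.34% ± 0.181 and 3.79% ± 0.0479 in the same order, and chromosome 17 held 6.26% ± 0.302, 5.53% ± 0.177 and 5.03% ± 0.0131. Of the 23 chromosomes, 7 took a larger and 7 a smaller share in all 4 knockout libraries than in both control libraries. Chance gives 6.67% of chromosomes in each direction if all libraries are exchangeable. Libraries of a group resembled each other, so 6.67% is no benchmark for groups that differ. Shares within a library are also not independent, as a rise on some chromosomes lowers the share of others.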

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

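The shares of peaks on 4 chromosomes moved in opposite directions in the 2 knockouts, with both libraries of each knockout on its side of both control libraries. The difference between the knockouts was not tested. The CFL1 knockout minus the METTL3 knockout came to 1.01 percentage points on chromosome 19, where control held 6.37%, the CFL1 knockout 6.89% and the METTL3 knockout 5.89%. It was 0.786 on chromosome 16 (4.73%, 5.28% and 4.50% in the same order) and 0.514 on chromosome 22 (2.49%, 2.80% and 2.28%). On chromosome 6 it was -0.566 (4.88%, 4.54% and 5.11%). With 2 against 2 exchangeable libraries, chance sets both libraries of 1 knockout on a given side of control for 16.7% of chromosomes. The chance of both knockouts on opposite sides of control is lower and was not computed. Libraries of a group resembled each other, so 16.7% is no benchmark for groups that differ. On chromosome 19 the SD over 2 libraries was 0.279 in control, 0.366 in the CFL1 knockout and 0.0256 in the METTL3 knockout.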

How the results depend on the processing

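The comparisons of peaks per library, peaks found in both libraries and chromosomes 1 to 22 were chosen after seeing the data. No paired analysis was possible because the knockout libraries carry numbers that are not the labels' replicate numbers. Values below are given for control peaks lost in the CFL1 knockout, lost in the METTL3 knockout, CFL1 knockout peaks absent from control and METTL3 knockout peaks absent from control, in that order. They are given only where they moved by more than 1 SD between libraries. That SD was taken over the libraries of the list counted, each used alone, with the other list pooled. It leaves out the spread between libraries of the other list. With a peak shared at 50% of the shorter peak they were 60.4%, 60.1% and, for the METTL3 knockout gains, 52.2%. With the summit as position they were 62.6%, 62.1%, 58.8% and 54.9%. At a −log10 q of at least 5 they were 50.6%, 50.4% and, for the METTL3 knockout gains, 44.9%. At a fold of at least 4 they were 54.2%, 52.8%, 59.9% and 55.5%. At a −log10 q of at least 10 in the first list they were 34.6%, 33.6%, 32.9% and 29.3%. After merging peaks within 100 bp they were 62.8%, 62.9%, 60.4% and 56.1%. For peaks found in both libraries of the first list they were 48.7%, 48.4%, 37.6% and 36.5%. On chromosomes 1 to 22 none moved by 1 SD. With each library left out in turn they ran from 57.4% to 63.5%, 57.3% to 62.3%, 50.4% to 59.1% and 48.8% to 55.6%.

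The odds ratio of loss in both knockouts stayed above 1 in all 16 alternatives. It moved to 60.2 at a −log10 q of at least 10, 53.2 in bins of fold and 51.7 for peaks of both control libraries, and ran from 32.3 to 49.0 without each library. Peaks per list at a fold of at least 4 numbered 78595 in control, 88368 in the CFL1 knockout and 83692 in the METTL3 knockout. After merging they numbered 98914, 91978 and 81697, and at a −log10 q of at least 5 control held 100960. A list without 1 of its libraries held 77603 to 79467 peaks in control, 66295 to 72728 in the CFL1 knockout and 63859 to 64952 in the METTL3 knockout, by construction. Peaks per library relative to control were 0.885 in the CFL1 knockout and 0.820 in the METTL3 knockout. They reversed to 1.07 and 1.02 at a −log10 q of at least 10, 1.13 and 1.12 at 20, and 1.12 and 1.07 at a fold of at least 4, and were 0.987 and 0.892 at 5. For the METTL3 knockout, 2 of these reversals did not separate the libraries. At a −log10 q of at least 10, METTL3 knockout 5 held 32702 peaks against 33168 in control 2. At a fold of at least 4, METTL3 knockout 3 held 41014 against 41423 in control 1. Without each library the ratios ran from 0.844 to 0.926 and from 0.810 to 0.830. Except where named, the cause was not tested. The alternatives for gene lists, genes with an exonic peak, transcript regions and the DRACH motif were not run, since an hg19 annotation or genome was not used here. The read depth behind the calls is unknown, so a lost peak may lie just under a threshold, and of the weakest 10% of control peaks the other control library found 33.9%.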

Other observations

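Counts of peaks in 1-Mb windows and all tests here except those of copied peaks, for a batch and for duplicated sequence, were chosen after the result was seen. For the batch, the bound was set before copies were counted, but which peaks to count was settled after a first count. Counts are per 100000 peaks of the library. Of 1273 windows with a mean of at least 20 peaks over control and knockouts, 464 (36.4%) had a lower count in all 4 knockout libraries than in both control libraries, and 361 (28.4%) a higher one. Chance gives 6.67% each if all libraries are exchangeable. Libraries of a group resembled each other, so 6.67% is no benchmark for groups that differ, and a shared shift of the knockouts was not tested. The steepest fall was on chromosome X from 123 to 124 Mb, with 52.4 ± 9.90 in control, 5.10 ± 1.36 in the CFL1 knockout and 4.69 ± 2.26 in the METTL3 knockout (SD, n = 2). On chromosome 17 from 57 to 58 Mb the counts were 173 ± 18.3, 24.6 ± 1.62 and 35.1 ± 3.73, and from 49 to 50 Mb they were 80.4 ± 8.57, 8.75 ± 2.62 and 24.2 ± 3.60. Chromosome 15 from 50 to 51 Mb held 87.4 ± 4.18, 15.99 ± 3.09 and 23.4 ± 2.48.

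The windows with the steepest rise, among the same 1273, included chromosome 4 from 49 to 50 Mb, with 15.9 ± 2.44 in control, 82.7 ± 11.9 in the CFL1 knockout and 84.1 ± 3.40 in the METTL3 knockout (SD, n = 2). Chromosome 2 from 1 to 2 Mb held 28.01 ± 4.94, 111 ± 10.3 and 108 ± 6.41, and chromosome X from 63 to 64 Mb held 12.7 ± 3.39, 35.5 ± 3.35 and 59.97 ± 2.59. These windows were ranked by their size of change, so their values lean towards the extreme.

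Both knockouts stood apart from control in a like way. Strong peaks here had a −log10 q of at least 10 in both libraries of a group. Strong knockout peaks absent from control numbered 0.852 (CFL1) and 0.855 (METTL3) times the strong control peaks absent from the knockout. This ratio cannot decide whether loss of methylation at shared sites was the whole cause. Peaks are called relative to other signal in a library, so loss at some sites may alter calls at others, which was not tested. In the lists as deposited, lower sensitivity of the knockout libraries, as the whole cause, is argued against. Of the strong knockout peaks, 23.9% (CFL1) and 22.3% (METTL3) had no control peak. A batch or processing difference cannot be told apart from the genotype, since no folder in the peak names holds both control and knockout libraries. The share of missing peak numbers was 1.80 (CFL1) and 1.68 (METTL3) times that of control, and higher in all 4 knockout libraries, while the share of peaks with a −log10 q of at least 100 that had a copy of like shape in their library differed 1.37 times (4.37% in control, 5.97% in the knockouts). The ratio of copies lay under the 1.5 times set beforehand as the bound against a batch, but the bound was wrong, since a batch need not leave this mark and the design holds no control within a knockout batch.

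Strong peaks (−log10 q of at least 100) of a CFL1 knockout library with no peak in either control library numbered 384.5 ± 12.02, against 169.5 ± 74.2 of a control library with none in either CFL1 knockout library (SD, n = 2), and for the METTL3 knockout the numbers were 346.5 ± 30.4 and 111 ± 39.6. Reads placed at several copies of a duplicated sequence were tested by peaks of like width, summit and −log10 q in the same library. Such a copy was found for 12.9% of the strong CFL1 knockout peaks and 17.7% of the strong METTL3 knockout peaks absent from both control libraries, and for 13.6% of the strong control peaks absent from all 4 knockout libraries, a stricter set, against 3.92% to 5.87% of the strong peaks shared between control and knockouts. Counting mirrored summits too, which was tried first, after the bounds were set, and was not part of the test as set, gave 16.3% to 26.1% in the 4 knockout libraries and 20.9% and 23.9% in the control libraries. With either count the shares for the knockouts lie between the bounds of 10% and 50% set beforehand, so duplicated sequence stays open for part of these peaks, as does a biological difference between the genotypes, which was not tested.

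The lower number of peaks in the knockout lists is consistent with both removal of called peaks before deposit and a difference among peaks near the calling threshold, which the lists do not separate. For the removal, the highest peak number was 1.23 (CFL1) and 1.07 (METTL3) times that of control, and more numbers were missing in all 4 knockout libraries. For the threshold, at a −log10 q of at least 10 the knockouts held 1.07 (CFL1) and 1.02 (METTL3) times as many peaks per library as control. The METTL3 values of both lay within the spread between libraries. Loss of m6A in the METTL3 knockout stays open as untested, since a peak can stay called at a lower level of methylation.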
